A study of Mus musculus with 4 samples.

How the data were processed

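Nuclei were taken from adult mouse cortex by INTACT, in which a tag on the nuclear envelope protein Sun1 is switched on by a Cre driver so that nuclei of one cell type can be captured. The drivers were Sst-cre, which marks somatostatin interneurons, and Vip-cre, which marks vasoactive intestinal peptide interneurons. Per the labels' protocols, crosslinked chromatin was cut with MboI, contacts were captured by HiChIP with an antibody to H3K27ac, and libraries were made with Tn5. H3K27ac is a histone mark of active promoters and enhancers, and HiChIP is a chromatin contact assay that keeps the contacts carrying the precipitated mark. The labels describe 4 samples, 2 per cell type. One interaction list per cell type was analysed here, attached to replicate 1 of each; a list for replicate 2 was not analysed here, and whether each list pools both replicates is not given in the sources used here.

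The deposited files hold 6 columns without a header, namely the chromosome, start and end of each of the paired anchors of an interaction. They hold no read count, score or p-value per interaction. The submitters' processing notes name HiC-Pro and the mm9 genome build. The interaction caller, its threshold, the anchor set and its merging distance are not given in the sources used here. In both lists the smallest gap between neighbouring anchors was 501 bp, no anchors overlapped, no row was repeated and no interaction joined different chromosomes. Coordinates are printed as in the files, with build mm9; whether starts count from 0 or 1 is not stated, so a start may differ by 1 bp. On 4 of the 20 chromosomes the lists reach past the last gene of the GRCm38 gene table at hand, so that table was used only for this check. An mm9 annotation was not used here, and anchors were therefore not assigned to genes. For this reason the 16 gene lists and the promoter comparisons that had been planned were not run, and regions are named by coordinate.

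An interaction was counted as shared when both of its anchors overlapped, by at least 1 bp, the corresponding anchors of an interaction in the other list. Distances were measured between anchor midpoints. For windows of 1 Mb, which start at position 1 of each chromosome, each interaction was placed by the midpoint between its anchors, and counts were scaled to 1000 interactions of the list. The regions named were set by a rule fixed before the data were examined: the 5 anchors with the most interactions in each list (ties included) and the 10 windows with the largest difference in each direction. The limit of 200 kb, the 50% overlap, the 5 kb merging, the thinning, the moved windows and the removal of named windows were added after seeing the data. Chance overlap was described with 1000 circular shifts of the VIP list along each chromosome, by at least 5 Mb. These shifts do not keep the positions of the lists relative to genes or other features of a chromosome.

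With 1 list per cell type there was no replicate spread, and no p-value was computed. Intervals are exact 95% binomial (Clopper-Pearson) or Poisson intervals, and order-statistic intervals for medians. They cover counting error only and take interactions as independent, although interactions share anchors. A standard error from leaving out each chromosome in turn is given for some list-wide values. It covers variation along the genome and not between animals. Other list-wide values carry an exact interval alone, which can be too narrow. For the shared percentage of SST interactions, the exact interval was 20.6 to 22.3% while this standard error was 1.45 percentage points. Sequencing depth per library is not in the lists and is unknown here, so the length of a list cannot be separated from depth. An interaction missing from a list was not called there, which does not show that the contact is absent.

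Alternatives covered identical anchors, anchors within 10 kb, an overlap of at least 50% of the shorter anchor, distances of 20 kb to 2 Mb, distances of up to 200 kb, autosomes only, merged anchors, moved windows, SST thinned to the length of VIP and lists without the 20 named windows. On simulated lists of 8278 and 6733 interactions, the overlap step found 2000 of 2000 planted shared interactions and made 0 false calls. The simulated interactions were spaced so that unrelated ones could not overlap. This checks the code and gives no rate of chance matches in the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.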

Results

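H3K27ac HiChIP interactions were compared between nuclei of somatostatin (SST) and vasoactive intestinal peptide (VIP) interneurons, 2 classes of inhibitory neuron, from adult mouse cortex. The SST list held 8278 interactions between 5842 distinct anchors, and the VIP list held 6733 interactions between 4850 anchors. Anchors had a median width of 11782 bp in SST and 12355 bp in VIP and covered 85.2 Mb and 72.7 Mb of the genome. Only 1 list per cell type was analysed and none for replicate 2, so the values below describe these lists and were not tested against a spread between animals. The read depth behind the lists is unknown, and coordinates are mm9.

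The comparison asked which genomic regions had acetylated chromatin contacts listed mainly for one of the interneuron classes. The largest difference in favour of SST lay on chromosome 9 between 28 and 29 Mb, which held 118 SST interactions and 3 VIP interactions, or 14.3 against 0.446 per 1000 of each list. That is a 32.0-fold difference with a counting interval of 10.7 to 157. The window was picked as the largest difference, which the interval does not take into account. Its 118 SST interactions joined only 37 anchors and are therefore not independent. The next window, 29 to 30 Mb on the same chromosome, held 65 SST and 15 VIP interactions. On chromosome 17, the window from 11 to 12 Mb held 82 SST interactions and the window from 67 to 68 Mb held 46, and neither had a VIP interaction. No VIP interaction was listed either for chromosome 8 from 88 to 89 Mb (64 in SST), chromosome 7 from 122 to 123 Mb (53 in SST) or chromosome 14 from 24 to 25 Mb (45 in SST). The remaining SST windows of the named 10 were chromosome 8 from 121 to 122 Mb (64 against 1), chromosome 11 from 56 to 57 Mb (79 against 14) and chromosome 16 from 9 to 10 Mb (61 against 2).

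The largest difference in favour of VIP lay on chromosome 12 between 29 and 30 Mb, with 69 VIP interactions and 1 SST interaction. No SST interaction was listed for chromosome 4 from 75 to 76 Mb (65 in VIP), chromosome 19 from 48 to 49 Mb (61 in VIP) or chromosome 7 from 118 to 119 Mb (57 in VIP). The window on chromosome 17 from 49 to 50 Mb held 54 VIP interactions and 1 SST interaction. The windows on chromosome 7 from 38 to 39 Mb and on chromosome 8 from 16 to 17 Mb each held 46 VIP and 2 SST interactions. Chromosome 2 from 157 to 158 Mb held 49 against 7. Chromosome 17 from 25 to 26 Mb differed least in proportion among these windows, with 77 VIP and 35 SST interactions, a 2.70-fold difference per 1000 with an interval of 1.79 to 4.16. This interval likewise does not take into account that the window was chosen for its difference. Of its 77 VIP interactions, 22 were also in the SST list, while the window on chromosome 12 from 29 to 30 Mb had 1 shared interaction of 69. On chromosome 8 the window from 122 to 123 Mb held 55 VIP and 5 SST interactions, directly beside the window from 121 to 122 Mb that was higher in SST. The SST interactions of the first window ran from 120573680 to 121871253, and the VIP interactions of the second ran from 121976945 to 123116876.

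**Figure D1:**
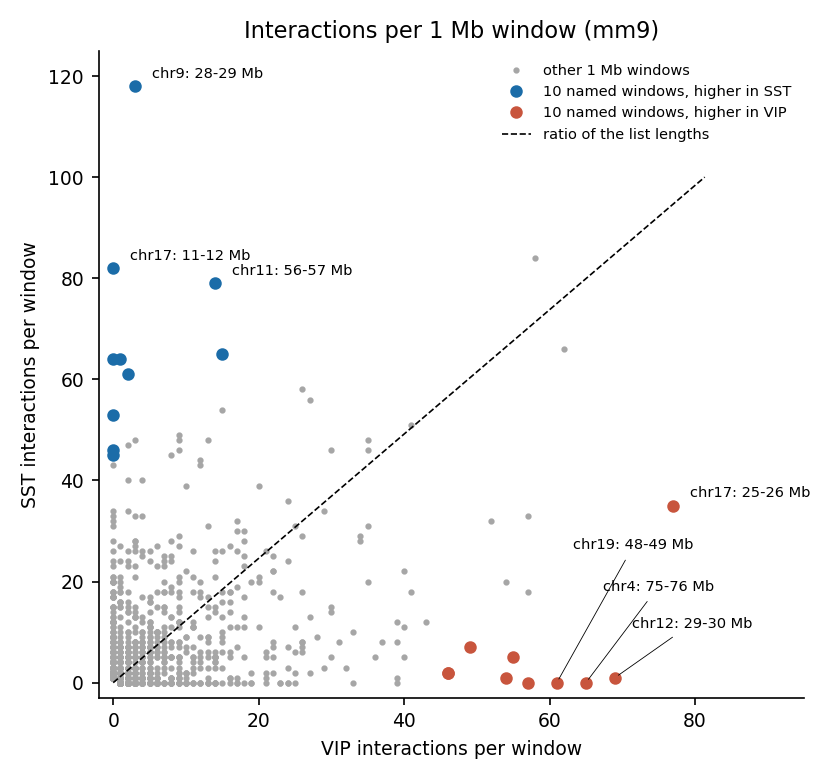
Number of interactions in each 1 Mb window of the mm9 genome in the VIP list (x axis) and the SST list (y axis); each point is a window, the coloured points are the 10 named windows in each direction, and the dashed line is the ratio of the list lengths. The window on chromosome 9 from 28 to 29 Mb has 118 SST and 3 VIP interactions, and the window on chromosome 12 from 29 to 30 Mb has 1 SST and 69 VIP interactions.

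Across the genome, 1160 windows held at least 1 interaction. Of these, 599 had interactions from both lists, 327 from SST alone and 234 from VIP alone. Among the 242 windows with 20 or more interactions, 42 were filled by SST, meaning that at most 10% of their interactions came from VIP, and 25 were filled by VIP. When the interactions of each window were assigned to the lists at random by list length, no more than 1 window was filled in either direction in any of 1000 draws, although these draws ignore that interactions share anchors. The 10 SST windows held 677 SST and 35 VIP interactions, 8.18% of the SST list, and the 10 VIP windows held 579 VIP and 53 SST interactions, 8.60% of the VIP list. In its higher list a named window had between 15 anchors (chromosome 17 from 67 to 68 Mb) and 37 anchors (chromosome 9 from 28 to 29 Mb). Its interactions are links among these few anchors, and their number depends on how the anchors were divided. Of the interactions of up to 200 kb, 31 SST and 0 VIP interactions lay on chromosome 9 from 28 to 29 Mb, and 34 VIP and 0 SST interactions lay on chromosome 19 from 48 to 49 Mb; these are part of the counts by which the windows were chosen and no separate test of them.

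**Figure D2:**
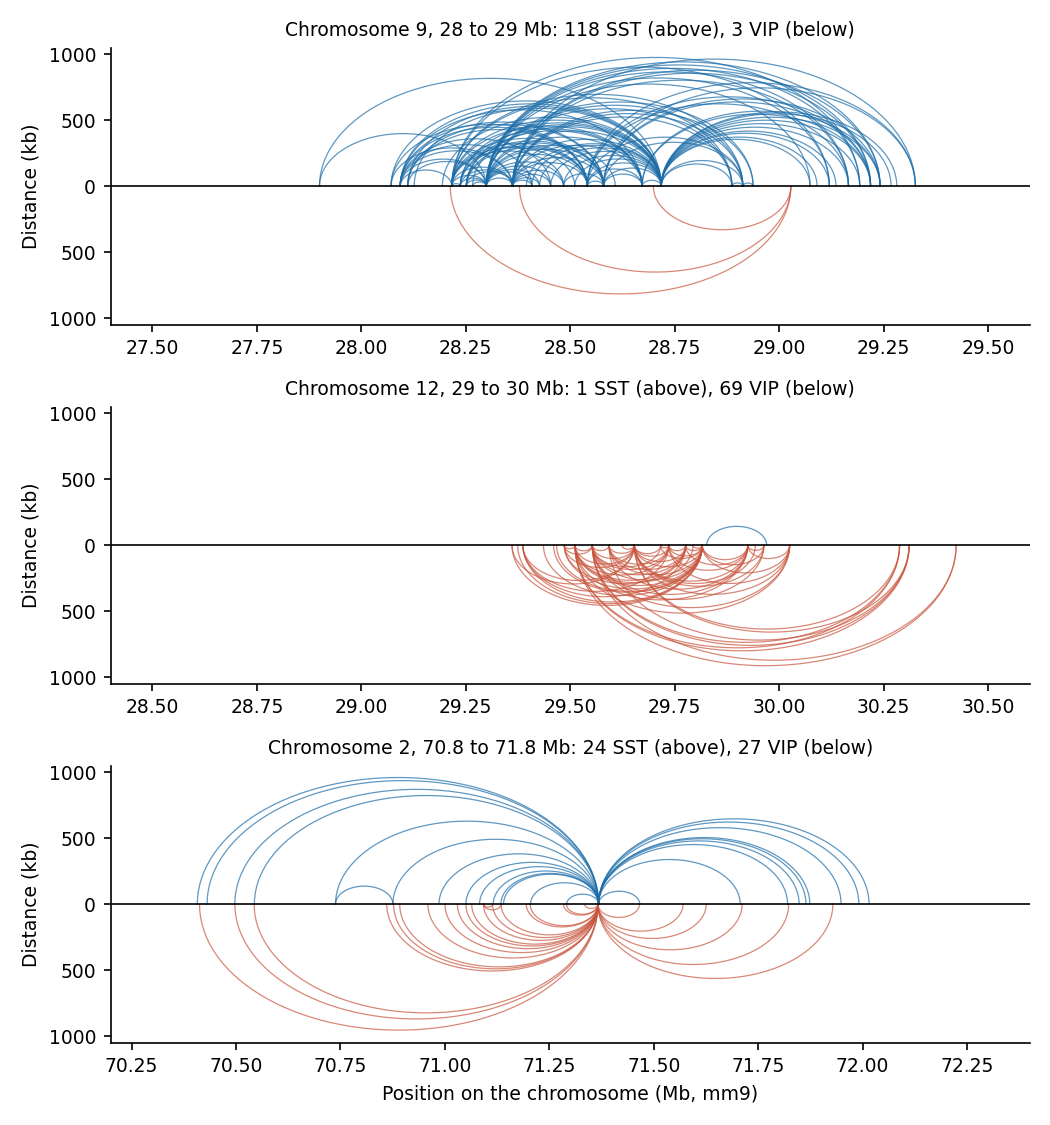
Interactions whose midpoint lies in 3 regions of 1 Mb (mm9), drawn as arcs between anchor midpoints, SST above the line and VIP below it; the x axis is the position in Mb and the height of an arc is the distance between the anchors in kb. Chromosome 9 from 28 to 29 Mb has 118 SST and 3 VIP interactions, chromosome 12 from 29 to 30 Mb has 1 and 69, and chromosome 2 from 70.8 to 71.8 Mb has 24 and 27, of which 15 are shared.

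The most connected anchors included loci with many listed interactions in both lists and loci with many in one list and few or none in the other. In SST, the anchor at chromosome 9, 28686966 to 28749132, took part in 44 interactions (Poisson interval 32.0 to 59.1), and the VIP anchor overlapping it took part in 1. A second anchor of the same region, at 28271959 to 28326276, had 26 SST interactions and no overlapping VIP anchor. The chromosome 7 anchors at 123165883 to 123191014 and at 122642471 to 122728442 had 29 and 26 SST interactions, and neither overlapped a VIP anchor. The anchor at chromosome 3, 34531738 to 34577892, had 32 SST interactions, of which 19 were also listed in VIP. In VIP the corresponding anchor, 34531738 to 34574387, had 23 interactions, of which 17 were also listed in SST. The anchor with the most VIP interactions was at chromosome 2, 71345229 to 71387539, with 25, and the overlapping SST anchor had 23; of the 25 VIP interactions, 15 were shared.

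A further 6 VIP anchors, the one on chromosome 3 included, were tied at 23 interactions. The anchor at chromosome 12, 54664991 to 54761796, was 96.8 kb wide and overlapped 3 SST anchors with 46 interactions in sum. The anchor at chromosome 5, 111842823 to 111881810, overlapped an SST anchor with 10 interactions, and that at chromosome 17, 56494730 to 56552368, overlapped 3 SST anchors with 15 in sum. The anchors at chromosome 2, 28041636 to 28090320, and at chromosome 17, 25690275 to 25718431, overlapped SST anchors with 1 and 4 interactions. Busy anchors were also wide, with a median width of 34.9 kb in SST and 34.8 kb in VIP at 10 or more interactions against 8.69 and 9.17 kb at 1. When anchors within 5 kb were merged, a setting added after seeing the data, the highest number of interactions at an anchor went from 44 to 27 in SST and from 25 to 20 in VIP. Over each whole list, an anchor took part in a median of 2 interactions in each list, and 34.4% ± 0.766 of SST anchors and 33.5% ± 1.12 of VIP anchors took part in 3 or more (SE over chromosomes left out in turn). Across the 2320 pairs of overlapping anchors, the numbers of interactions in SST and VIP had a Spearman correlation of 0.26, a value across anchors, which are not replicates.

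A minority of contacts was listed in both cell types. In the SST list 1775 interactions, 21.4% ± 1.45 (SE over chromosomes, exact interval 20.6 to 22.3%), had a counterpart in VIP, and in the VIP list 1740 interactions, 25.8% ± 1.32 (24.8 to 26.9%), had one in SST. Shifted lists shared 0.853% and 1.04% on average and at most 1.61% and 2.15%. Anchors were shared more often, at 36.9% ± 1.63 in SST and 43.5% ± 1.45 in VIP, against 5.23% and 6.24% for shifted lists. Of the 6503 interactions found in SST only, 51.1% (49.9 to 52.4%) had neither anchor in the VIP list, 38.5% had one and 10.4% had both. Of the 4993 interactions found in VIP only, 45.8% (44.4 to 47.2%) had neither anchor in the SST list, 42.5% had one and 11.8% had both. These intervals cover counting error alone, so they do not set the lists apart. When SST was thinned to the length of VIP, 21.5% of SST and 21.6% of VIP interactions were shared. Random thinning leaves the SST share about unchanged and lowers the VIP share by construction. It does not stand in for a lower read depth.

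Where both anchors of a pair were listed in both cell types, most links were listed in both. Of 2449 SST interactions whose anchors both overlapped VIP anchors, 72.5% (70.7 to 74.2%) were also listed in VIP. Of 5883 pairs of such anchors within 1 Mb that were not linked in SST, 18.5% (17.5 to 19.5%) were linked in VIP. From the VIP side the values were 74.8% of 2327 linked pairs and 18.4% of 5493 unlinked pairs. The percentages of unlinked pairs count pairs of anchors and not distinct links, since an anchor can overlap several anchors of the other list. They cover 1086 and 1012 pairs, against 587 VIP-only and 674 SST-only interactions with both anchors in the other list. The linked pairs were higher in each of the 6 distance classes, at 70.9% against 32.8% up to 50 kb and 53.9% against 6.30% above 600 kb in SST, and at 76.7% against 36.8% and 66.2% against 7.56% in VIP. An anchor appears in a list only through an interaction, which bears on both percentages.

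Distances spanned 6.69 to 999.7 kb in SST and 6.76 to 995.5 kb in VIP. The median distance was 178 kb ± 11.9 in SST and 167 kb ± 9.70 in VIP, a difference of 10.7 kb ± 10.6 (SE over chromosomes), which is about the size of its standard error. The SST median was the longer one on 11 of 20 chromosomes, and among interactions of up to 200 kb the medians were 54.9 kb and 56.3 kb. The number of interactions did not decline evenly with distance in either list. In bins of 20 kb between 100 and 400 kb it dropped to 102 SST interactions at 240 to 260 kb and stood at 272 at 320 to 340 kb, and it dropped to 99 VIP interactions at 220 to 240 kb and stood at 236 at 280 to 300 kb. Interactions of 200 to 400 kb made up 23.3% of SST (22.4 to 24.3%) and 25.7% of VIP (24.7 to 26.8%), and those of 400 to 600 kb made up 14.7% (13.9 to 15.5%) and 12.7% (11.9 to 13.5%). Intervals of these shares cover counting error alone and do not set the lists apart. Within the 10 named SST windows the median distance ranged from 176 kb on chromosome 14 from 24 to 25 Mb to 482 kb on chromosome 11 from 56 to 57 Mb. Within the 10 named VIP windows it ranged from 128 kb on chromosome 17 from 25 to 26 Mb to 369 kb on chromosome 8 from 16 to 17 Mb.

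**Figure D3:**
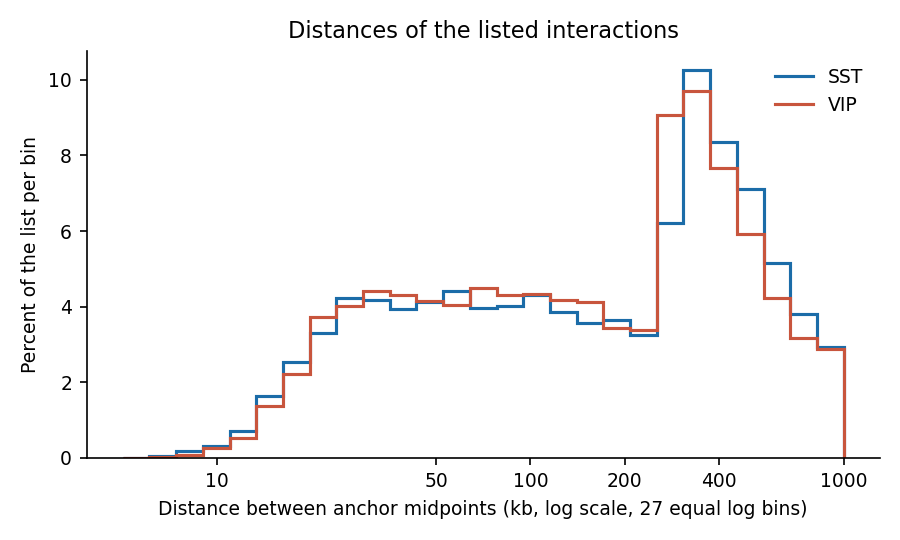
Distance between anchor midpoints (x axis, kb, log scale) against the percent of the SST or VIP list in each of 27 bins of equal log width. Both lists are about level between 50 and 200 kb and step up in the bin that starts at 253 kb, where VIP stands above SST.

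Interactions found in one cell type only were longer than shared ones. The medians were 198 kb ± 14.6 for SST-only and 119 kb ± 17.9 for shared SST interactions, a difference of 78.6 kb ± 23.2, and 187 kb ± 13.1 against 118 kb ± 13.4 in VIP, a difference of 69.5 kb ± 15.4. The difference had this sign on 15 of 20 chromosomes in SST and 16 of 20 in VIP. Among interactions of up to 200 kb it shrank to 2.32 kb in SST and 5.47 kb in VIP, and without the 20 named windows it was 52.7 kb and 53.5 kb. Sharing was 25.1% (23.2 to 27.1%) up to 50 kb and 12.7% (10.5 to 15.2%) above 600 kb in SST, and 30.1% (27.9 to 32.5%) and 18.0% (14.9 to 21.4%) in VIP. The values did not decline evenly between these classes, but the departures lay within overlapping intervals. In both lists sharing was highest at 50 to 100 kb, with 26.3% (23.8 to 28.8%) in SST and 30.9% (28.1 to 33.9%) in VIP. These intervals overlap those up to 50 kb. In VIP sharing was 22.2% (20.3 to 24.3%) at 200 to 400 kb and 25.2% (22.3 to 28.3%) at 400 to 600 kb, which also overlap. A wider anchor meets the 1 bp overlap more easily. Shared anchors had a median width of 12.5 kb against 11.4 kb for other anchors in SST, and 13.2 against 11.8 kb in VIP. With anchors within 10 kb the difference in median distance was 101 kb in SST and 94.2 kb in VIP. Interactions of matched anchor width were not compared, so the part of width was not tested.

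**Figure D4:**
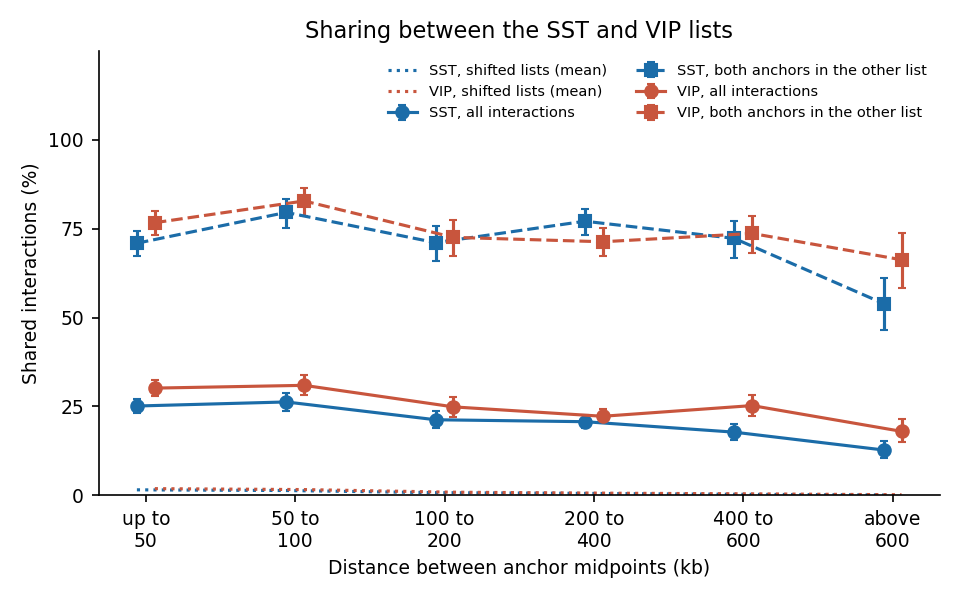
Percent of interactions shared with the other list (y axis) by distance class in kb (x axis), for SST and VIP; circles are all interactions, squares are those with both anchors in the other list, bars are exact 95% intervals and dotted lines are the mean of shifted lists. Among all interactions, sharing is 25.1% up to 50 kb and 12.7% above 600 kb in SST, and 30.1% and 18.0% in VIP.

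The SST list was 1.23 times as long as the VIP list (SE over chromosomes 0.0531), and 17 of 19 autosomes had more SST interactions. Chromosome 9 had the highest ratio of SST to VIP, 534 against 320 interactions or 1.67 (1.45 to 1.92), which was 1.16 without the named windows. Chromosomes 15 and 3, which hold no named window, had ratios of 1.52 (1.30 to 1.78) and 1.49 (1.27 to 1.76). Chromosome 12, with 446 against 489, had the lowest autosomal ratio, 0.912 (0.800 to 1.04), and was at 1.06 without the window from 29 to 30 Mb. Chromosome 4, at 0.971, was at 1.14 without the window from 75 to 76 Mb. Chromosome 19 was at 1.17 with the window from 48 to 49 Mb and at 2.01 without it. Chromosome X held 7 SST and 11 VIP interactions, 0.120% of the 15011 listed. Over both lists this was 0.112 interactions per Mb, against a median of 5.75 on the autosomes and 3.91 on chromosome 3, the lowest of them.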

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

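The 20 named windows kept their direction when interactions were counted by either anchor, with differences of 5.44 to 16.6 per 1000, which is no separate test, as they were chosen on the same interactions; 40 SST-filled and 22 VIP-filled windows were found with windows moved by 500 kb. Identical anchor coordinates left 0.217% of SST and 0.267% of VIP interactions shared and 3.24% and 3.90% of anchors; linked shares where both anchors were present were then 75.0% of 24 (53.3 to 90.2%) and 90% of 20 (68.3 to 98.8%), too few to set apart from the shares with 1 bp overlap. Anchors within 10 kb gave 28.6% and 33.6% of interactions, 43.4% and 50.5% of anchors, and linked shares of 77.4% and 78.6%; SST-only interactions with neither anchor in VIP were then 52.7%, and the VIP-only minus shared median was 94.2 kb. An overlap of at least 50% of the shorter anchor gave 20.6% and 24.8% of interactions. Thinning SST to the length of VIP gave 21.6% for VIP, a fall that random thinning gives by construction. At 20 kb to 2 Mb the medians were 206 kb in SST and 188 kb in VIP. No listed distance exceeded 999.7 kb, so this setting only left out interactions under 20 kb, which raises the medians by construction. At up to 200 kb the medians were 54.9 and 56.3 kb, with 24.3% and 29.0% of interactions shared. The own minus shared medians were then 2.32 and 5.47 kb, as interactions above 200 kb are left out by construction. Without the 20 named windows the medians were 162 kb in SST and 157 kb in VIP. Sharing was then 23.0% and 27.8%, and the own minus shared medians were 52.7 and 53.5 kb. Sharing rises here largely by construction, as these windows were picked for a difference between the lists. Merging anchors within 5 kb left 30.7% of SST and 30.2% of VIP anchors with 3 or more interactions; merging overlapping or touching anchors changed nothing, since none overlap or touch. Where not stated, the cause was not tested. The settings chosen after seeing the data were the 50% overlap, the thinning, the 5 kb merging, the moved windows, the count by either anchor, the 200 kb limit, the removal of named windows and the 10 kb setting for interactions with neither anchor in the other list. Alternatives that rank interactions (equal or stricter lists) or use their counts were not run, as the lists hold no such value, and those on promoters and gene lists were not run without an mm9 annotation. No paired analysis was possible because each cell type has 1 list with no value per replicate, and no replicate could be left out. Depth is unknown, so an interaction missing from a list was not called there, and whether the contact was absent or below detection was not tested.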

Other observations

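The tests of list length, of library against cell type, of chromosome X and of a calling threshold were chosen after the result was seen, as were the windows rich in both lists named here and, for the step in distance, the ranges of 140 to 240 and 300 to 400 kb, which were picked from the distance plot. Some regions were rich in both cell types. Chromosome 12 from 54 to 55 Mb held 84 SST and 58 VIP interactions, of which 49 and 45 were shared, and chromosome 2 from 30 to 31 Mb held 66 and 62, of which 42 and 43 were shared. Chromosome 5 from 126 to 127 Mb held 51 and 41, with 16 and 12 shared. Chromosome 12 from 90 to 91 Mb held 48 and 35, with 9 shared on each side, and chromosome 7 from 98 to 99 Mb held 46 and 35, with 5 and 4 shared. In the windows on chromosomes 5 and 7 and the latter on chromosome 12, most interactions had no listed counterpart. The same held for the whole lists, where 21.4% of SST and 25.8% of VIP interactions were shared.

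Busy anchors differed in how their partners were placed. The SST anchor at chromosome 7, 123165883 to 123191014, had 29 of its 29 partners at lower positions, and the VIP anchor at chromosome 5, 111842823 to 111881810, had 20 of 23 at higher positions, while the SST anchor at chromosome 9, 28686966 to 28749132, had 21 on one side and 23 on the other. Among anchors with 6 or more interactions, 19.9% of 750 in SST (17.1 to 22.9%) and 19.1% of 598 in VIP (16.0 to 22.4%) had at least 90% of their partners on one side. Partners drawn 1000 times from the listed anchors at matched distances gave 14.5% (central 95% of draws 13.3 to 15.6%) and 14.9% (13.9 to 16.1%). The hypothesis that the placement of the other anchors alone sets this predicted values within the draws. The observed excess was 4.14 percentage points in VIP and 5.40 in SST. In VIP the counting interval of the observed value just reached the central 95% of the draws, so the excess is less clear there. Anchors with 10 or more interactions were listed in the other cell type in 51.7% (45.5 to 58.0%) of cases in SST and 57.0% (50.0 to 63.8%) in VIP, against 28.9% and 36.8% of anchors with a single interaction. Their median widths were 34.9 and 34.8 kb against 8.69 and 9.17 kb, and a wider anchor meets the 1 bp overlap more easily. Anchors of matched width were not compared, so width and number of interactions cannot be told apart here. Wide anchors held more interactions, with a Spearman correlation of 0.62 across SST anchors and 0.63 across VIP anchors. Sharing was lower in the longest than in the shortest distance class also after subtracting the sharing of shifted lists, by 10.9 percentage points in SST and 10.4 in VIP. Shifted lists shared only 1.55% in the shortest and 0.116% in the longest class in SST, and 1.88% and 0.163% in VIP. Subtracting them could therefore change the difference little. As a ratio to the shifted lists, sharing was higher in the longest class than in the shortest in both lists. Among interactions with both anchors in the other list, the difference between these classes was 17.0 points in SST and 10.4 in VIP, where the exact intervals of the classes overlap. Weighted to the same distance classes, the percentage of linked anchor pairs differed by -7.92 points in SST and -11.0 in VIP between pairs with and without a common partner, but the sign was not the same in each class (36.5 against 90.2% up to 50 kb and 14.2 against 3.76% above 600 kb in VIP, with the same signs in SST), and the comparison decides nothing, as an anchor without a common partner is listed only because it has a link.

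The step in the distance distribution differs from the smooth decline with distance that contact counts usually have. These lists hold called interactions and no counts, and the caller is unknown here, so whether they should decline smoothly is not known. In bins of 20 kb between 100 and 400 kb, the highest later bin held 2.67 times as many interactions as the lowest bin in SST and 2.38 times in VIP, and the lowest bin of this range lay at 240 to 260 kb in SST and 220 to 240 kb in VIP. Had regions filled by one list made the step, it would vanish without them or among shared interactions, yet the ratio of interactions of 300 to 400 kb to those of 140 to 240 kb was 1.47 and 1.43 without the 67 filled windows and 1.49 and 1.44 among shared interactions in SST and VIP, with a lowest lower bound of 1.17, which argues against those regions as the whole cause. On 18 of 19 autosomes in each list the later range held more interactions, which decides nothing on a calling threshold that loosens with distance, since the ranges were picked from the plot and a property of chromatin would give the same; the narrower anchor of a pair was also smaller beyond the step, at 10.5 against 14.4 kb in SST and 11.5 against 14.0 kb in VIP. Such a threshold and a property of chromatin in these neurons cannot be told apart from lists without counts, and both stay open.

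Windows filled by one list occurred in both directions. The longer SST list cannot by itself fill windows with VIP interactions, and 25 windows were filled by VIP beside 42 by SST. For the named windows only, a single hub anchor is argued against as well. The busiest anchor took part in a median of 27.2% of the interactions of a named window (quartiles 24.6 and 29.8%, range 17.1 to 47.2%). The named windows were chosen for their large differences, and not all of them are filled by one list. The filled windows that were not named were not tested for a hub anchor. The explanation of library rather than cell type stays open, because with 1 list per cell type the animal, the library and the cell type cannot be told apart. A candidate explanation is that these are regions of dense acetylated contact specific to somatostatin or vasoactive intestinal peptide interneurons. It was not tested, and a second list of each type or gene expression would bear on it. As HiChIP keeps contacts that carry the mark, a difference in H3K27ac and one in contact cannot be told apart from these lists.

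Chromosome X was nearly empty in both lists. A linear effect of a single X copy would leave its density at no less than 25% of the autosomal median by a bound that was set after the counts had been seen, and the density was 1.95% of it, with an upper 95% Poisson bound of 3.08%. A threshold set for autosomal coverage, which could remove most contacts of a chromosome with lower coverage, cannot be told apart from a filter on X or a true lack of contacts. Listed X anchors stood at 2.88% and 4.76% of the autosomal median per Mb in SST and VIP, but the lists hold only anchors with an interaction. The sex of the animals was not used here.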
